A study of Strongylocentrotus purpuratus with 9 samples.

How the data were processed

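The 9 samples of the purple sea urchin, Strongylocentrotus purpuratus, were labelled as 2 dpf (days post fertilisation) gastrulae. Single-cell RNA libraries were made from dissociated whole embryos in 5 samples, and ATAC-seq libraries from isolated guts in 2 samples and from whole embryos in 2 samples. ATAC-seq inserts sequencing adapters into accessible DNA with the Tn5 transposase, so that read pile-ups mark open chromatin. Guts were separated from embryos mechanically after a calcium- and magnesium-free wash, per the labels' protocols.

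The data used here were 1 file, a list of open chromatin regions for the whole series. It has 4 columns and no header: a scaffold, a first and a last coordinate in bp, and a region name that begins with pCRM and ends in a number. The descriptions of the 4 ATAC-seq samples name this list, and no column in it belongs to a library or a tissue. The submitters' processing notes name Trimmomatic 0.38, Bowtie2 2.3.4.1, SAMtools 1.7.1, bedtools 2.27.1, MACS2 2.1.2, Cell Ranger 3.0.2 and Seurat 3.0.2, with no role or order. The genome build, the peak-calling threshold, the treatment of Tn5 offsets, and whether regions were called per library or on pooled reads are not given in the sources used here. The deposited list carries no read depth, score, fold enrichment or q-value, so the depth behind a region is unknown, and no interval or detection floor that needs it is given.

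Because of what the list holds, several planned tests were not run. Gut and whole embryo accessibility were not compared, since the regions are not separated by library or tissue. Genes were not assigned to regions, and the place of regions relative to promoters, exons and introns was not analysed here, since the only annotation at hand was a gene table of assembly Spur_5.0 and the build of the list is not given. Consensus sites and GC content were not analysed here, since no genome sequence was used. The gene lists, marker lists and rule for named genes fixed before the data were examined therefore applied to no gene. The single-cell libraries were not analysed here.

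Coordinates were read as starting from 0 with the last coordinate excluded, because 33 regions start at coordinate 0. They are printed counting from 1. Width was the last minus the first coordinate, and a gap was the distance from the end of a region to the start of the next on the same scaffold. Scaffold lengths were not used, and the end of the last region on a scaffold, called its extent below, is a lower bound on its length. Intervals at the 95% level came from 1000 bootstrap draws of whole scaffolds. They cover the variation between scaffolds and not that between libraries or animals. Regions are not biological replicates, and a p-value below describes positions within this list.

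Spacing was compared with random placement, a test added after the list had been examined. On every scaffold with 3 or more regions, the first and last region, all widths, the summed gap length and the smallest gap of the list (301 bp) were kept, and the gaps were drawn anew 1000 times. The two-sided p-value of this test cannot go below 0.002. On simulated lists with the same 26587 gaps and 100 placements each, it called 1 of 40 uniform lists and 40 of 40 lists in which 2% of gaps had been shortened to under 2000 bp. These lists were drawn by the same random placement, so they do not show how the test behaves when regions are missing from a list. Windows of 100 kb that start at a region were compared with 200 placements, chains of regions with gaps of up to 2000 bp with 1000 placements, and rank correlations across regions with 1000 shuffles within scaffolds. Benjamini-Hochberg adjustment was applied over the 9 gap classes and over the 3 rank correlations, and all other p-values are unadjusted. The regions and scaffolds named below are the extremes of each measure and were chosen after their values were seen. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.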

Results

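The study profiled the gastrula of the purple sea urchin to draft a gene regulatory network of its gut, and combined chromatin accessibility with single-cell expression for that purpose. ATAC-seq was carried out on 2 libraries of isolated gut and 2 libraries of whole embryos at 2 dpf, and 5 single-cell RNA libraries were made from whole embryos of the same stage. The accessibility data were represented by a single list of open chromatin regions without values per library, so the list is described as a whole and the gut was not compared with the whole embryo. Open chromatin regions of this kind are commonly taken as candidate promoters and enhancers.

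The list held 30866 open chromatin regions on 3836 scaffolds. They did not overlap each other and covered 11.2 Mb in all, which was 1.60% of the 701 Mb between the first base of these scaffolds and the end of their last region. Scaffold3 carried the most regions, 141 over an extent of 2.33 Mb, followed by Scaffold10 with 99 and Scaffold20 with 90. Counts per scaffold were uneven, with 1344 scaffolds (35.0%) that carried 1 region each. The 460 scaffolds with 20 or more regions carried 16161 regions, or 52.4% of the list. These counts were not adjusted for extent, and a longer scaffold holds more regions at the same density.

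The regions were narrow. The median width was 303 bp (95% scaffold bootstrap interval 301 to 305 bp), the middle 50% of regions lay between 225 and 463 bp, and the mean was 363 ± 229 bp (SD over the 30866 regions). A broad peak held 7919 regions (25.7%) of 220 to 300 bp. A second, sharp peak stood at exactly 100 bp with 583 regions, against 34 regions of 99 bp and 67 of 101 bp. Below it, 1298 regions (4.21%) were narrower than 100 bp, down to 1 bp, and 583 regions (1.89%) were wider than 1000 bp.

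**Figure D1:**
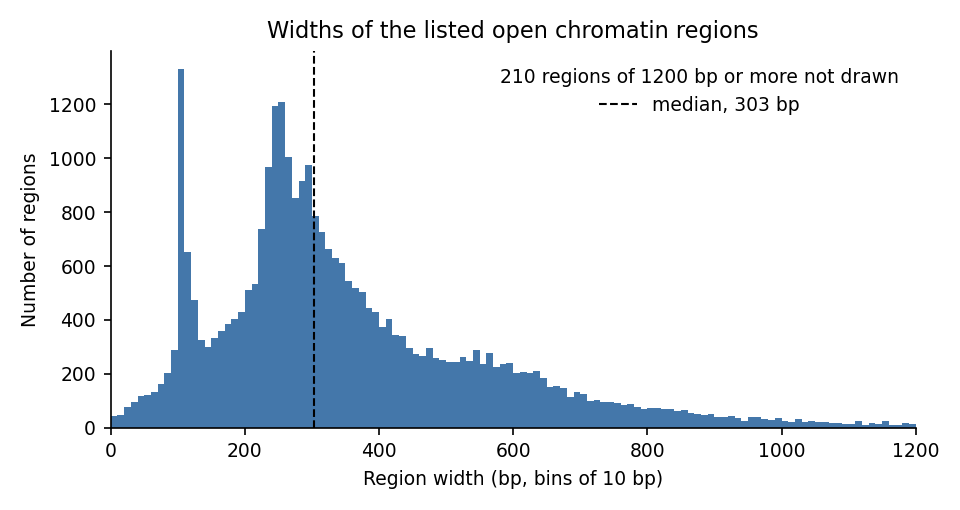
Number of regions (vertical axis) by width in bp (horizontal axis, bins of 10 bp) for the whole list, with the median of 303 bp as a dashed line. The sharp peak contains the 583 regions of exactly 100 bp, and the broad peak lies between 220 and 300 bp.

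The widest open chromatin regions were several times the median. The region pCRM_23193 spanned 2703 bp on Scaffold3051 (2898 to 5600), pCRM_17697 spanned 2647 bp on Scaffold2318 (68964 to 71610), and pCRM_41128 spanned 2603 bp on Scaffold790 (62331 to 64933). The next were pCRM_41667 on Scaffold811 with 2523 bp (223392 to 225914) and pCRM_27400 on Scaffold384 with 2450 bp (4676 to 7125). The genes at these positions were not analysed here.

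Open chromatin regions were more unevenly spaced than random placement on the same scaffolds gave, with more short gaps and a smaller median gap. Neighbouring regions were separated by a median of 9467 bp (95% scaffold bootstrap interval 9182 to 9760 bp over 27030 gaps), with the middle 50% between 3488 and 25539 bp and a range of 301 to 518649 bp. Of these gaps, 7450 contained a number that no region of the list bears, and the other 19580 had a median of 6330 bp. On scaffolds with 3 or more regions, the observed median gap was 9467 bp, while the placements gave a mean of 13460 bp and never less than 13167 bp. Gaps of up to 2000 bp made up 16.8% of 26587 gaps (95% interval 16.3 to 17.3%), against 9.03% on average under random placement (95% of placements between 8.71 and 9.34%), a ratio of 1.86 (permutation test over 1000 placements, two-sided p = 0.002, the smallest the placements can give).

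The excess was largest for the closest neighbours and became smaller with distance. Gaps of up to 1000 bp were 2.30 times as frequent as under random placement, those of 1000 to 2000 bp 1.53 times, those of 2000 to 5000 bp 1.13 times and those of 5000 to 10000 bp 1.08 times. Intermediate gaps were less frequent than under random placement, with ratios of 0.773 for 10000 to 20000 bp and 0.718 for 20000 to 50000 bp. Gaps of more than 50000 bp were again more frequent, with 11.6% observed and 9.79% under random placement. In runs of consecutive names, which contain no missing number, gaps of up to 2000 bp were 1.34 times as frequent as under random placement (23.0% against 17.1%), whereas those of 2000 to 5000 bp were less frequent, with a ratio of 0.921. Each of the 9 gap classes tested over all gaps, some of them nested, had an adjusted permutation p of 0.002, the smallest possible.

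**Figure D2:**
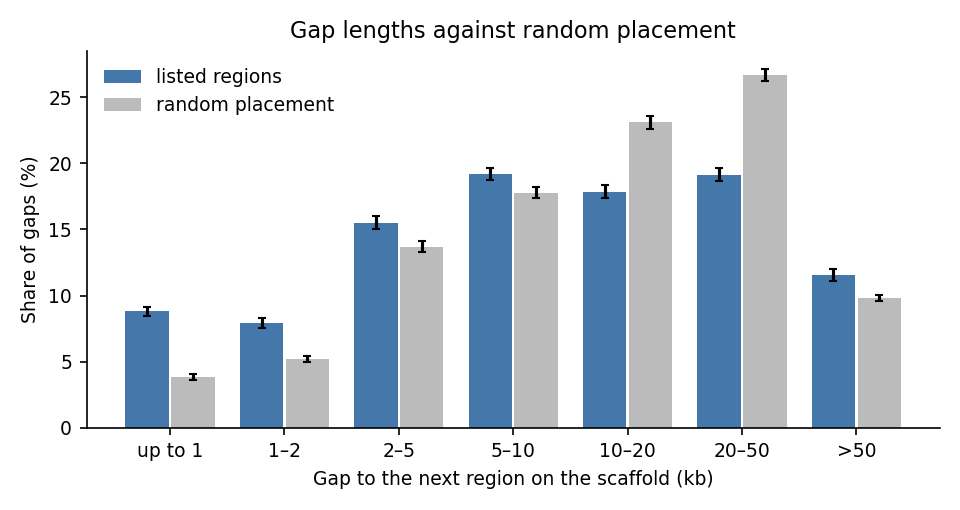
Share of gaps in percent (vertical axis) by gap length in kb (horizontal axis) for the listed regions (blue) and for random placement on the same scaffolds (grey). Error bars are 95% scaffold bootstrap intervals for the list and the range of 95% of the placements for random placement; over all gaps the listed regions exceed random placement up to 10000 bp and above 50000 bp, while in runs of consecutive names, not drawn, those of 2000 to 5000 bp fall below it.

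Chains were defined as successive regions with gaps of up to 2000 bp, and 8355 regions (27.1%) formed 3812 chains of at least 2 members. This share was not compared with random placement. There were 107 chains of 4 or more regions, whereas random placement gave 22.1 on average and at most 39 (permutation test, two-sided p = 0.002, the smallest the placements can give). The comparison of chains of 4 or more used all gaps and was not repeated in runs of consecutive names. The longest chains had 6 regions and were not longer than under random placement, which gave a longest chain of 5.41 regions on average and of up to 9. These 2 chains were pCRM_4557 to pCRM_4562 on Scaffold123 (930004 to 939863), where the regions covered 29.0% of 9860 bp, and pCRM_44132 to pCRM_44138 on Scaffold92 (296857 to 303262), where they covered 31.4% of 6406 bp. Among chains of 5 regions, pCRM_14112 to pCRM_14116 on Scaffold1954 (27079 to 33839) covered the most sequence, 2832 of 6761 bp (41.9%).

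In 2 windows of 100 kb, the listed regions were also more numerous than in any window of the random placements. This comparison used all gaps, with and without a missing number, and was not repeated in runs of consecutive names. The densest windows of 100 kb held 31 regions each, on Scaffold345 (303014 to 401973) and on Scaffold87 (243576 to 336771), against a maximum of 24.9 regions on average and of 28 at most in 200 random placements (permutation test, one-sided p = 0.00498, the smallest possible). The next windows held 26 regions on Scaffold243 (547232 to 646583), 26 on Scaffold468 (388792 to 486197) and 25 on Scaffold688 (191488 to 291217), which were within the range of the placements' maxima. In the window of Scaffold345 the regions covered 10.9% of the sequence with a median gap of 2649 bp, and in that of Scaffold87 they covered 8.70% with a median gap of 1902 bp. The window on Scaffold87 contained 2 of the chains of 5 regions, pCRM_42849 to pCRM_42853 and pCRM_42864 to pCRM_42868.

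**Figure D3:**
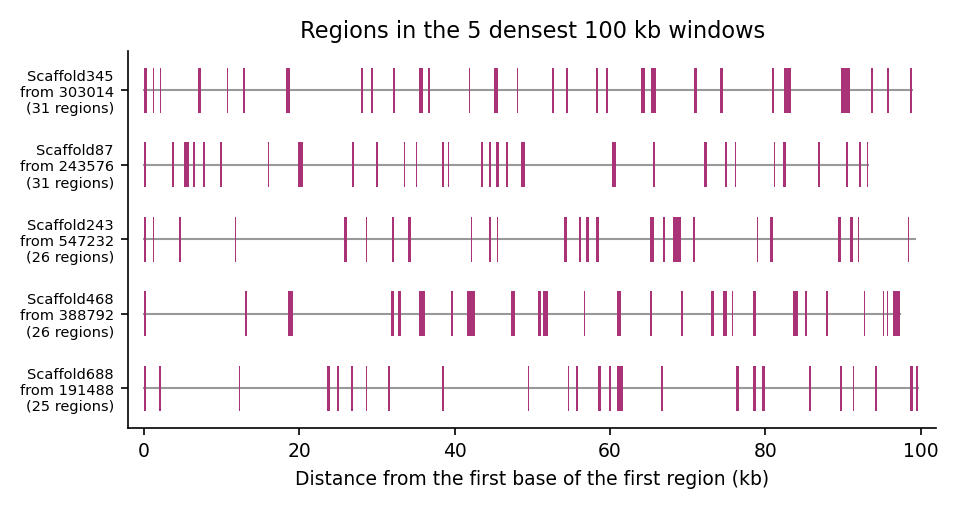
Positions of open chromatin regions (bars, to scale) in the 5 windows of 100 kb with the most regions; the horizontal axis is the distance in kb from the first base of the window's first region, and the labels give the scaffold, that base and the number of regions. The windows hold 25 to 31 regions, in groups separated by longer gaps.

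The observed density of listed regions varied between scaffolds. Over the 405 scaffolds with an extent of at least 500 kb, which held 13923 regions, the median was 4.09 regions per 100 kb, and the middle 50% lay between 3.13 and 5.06. These densities count listed regions only and divide by extents, which are lower bounds on scaffold length. Scaffold1396 (60 regions, 10.7 per 100 kb) and Scaffold520 (73 regions, 10.7 per 100 kb) were the densest, followed by Scaffold220 with 9.06 and Scaffold592 with 8.90 per 100 kb. The sparsest were Scaffold264 with 7 regions (0.964 per 100 kb), Scaffold98 with 5 (0.968 per 100 kb) and Scaffold497 with 6 (1.16 per 100 kb). The variance of the counts was 4.11 times that of a random allocation by extent. In 1000 draws the allocation gave 1.24 at most (permutation test, two-sided p = 0.002, the smallest possible). Each region was allocated independently of the others, so grouping of regions along scaffolds can also raise this variance. The test cannot tell such grouping from differences in underlying density between scaffolds.

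Region width was only weakly related to spacing. Regions with a neighbour within 1000 bp had a median width of 293 bp (4575 regions), those with the nearest neighbour at 1000 to 5000 bp 301 bp, those at 5000 to 20000 bp 314 bp, and those farther than 20000 bp 307 bp (4679 regions). Across 29522 regions, width and distance to the nearest region had a Spearman correlation of 0.04 and a Pearson correlation of 0.02 (permutation within scaffolds, two-sided adjusted p = 0.0015, 3 relations tested). The widths of neighbouring regions had a Spearman correlation of 0.02 and a Pearson correlation of 0.02 across 27030 pairs (adjusted permutation p = 0.020), against 0.01 on average after shuffling widths within scaffolds. These correlations are across regions, which are not independent replicates.

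The numbers in the region names rose along the list once it was sorted by scaffold name and start, and the highest was 45673. Of the numbers from 1 to 45673, 14807 (32.4%) were not used by any region in the list. Whether the submitters left those regions out or lines are missing from the copy analysed here is not known, so the count of regions and the gaps describe this list and need not describe all regions that were called. Of the missing numbers, 10892 fell between neighbouring regions of one scaffold, and the remaining 3915 between scaffolds or before the first region. Gaps without a missing number had a mean of 13146 bp (19580 gaps), and gaps with 1 missing number a mean of 32659 bp (5191 gaps), or 16330 ± 234 bp (SEM) per step between successive numbers.

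**Figure D4:**
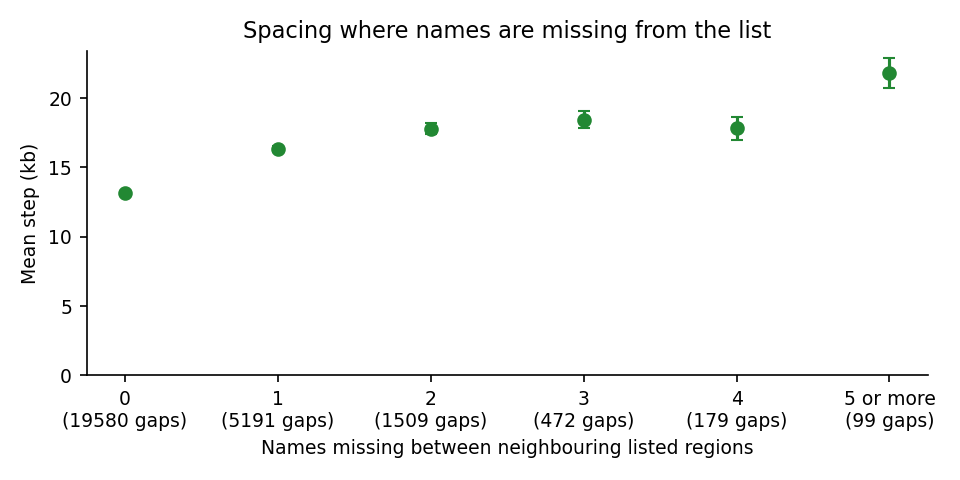
Mean step in kb between successive region numbers (vertical axis, bars are the SEM over gaps) by how many numbers are missing between neighbouring listed regions (horizontal axis). The mean step is 13146 bp with none missing and 16330 bp with 1 missing.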

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

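Of the alternatives that could be run, the merging of regions closer than 100 bp and the removal of short scaffolds were chosen before the data were examined; the others, and the test against random placement itself, were chosen after. Merging regions closer than 100 bp changed nothing, because the smallest gap was 301 bp. Leaving out scaffolds whose last region ended before 100000 bp, used in place of scaffold length, raised the median gap to 9787 bp. Merging regions closer than 1000 bp raised the median width to 323 bp and the median gap to 11097 bp, as merging removes short gaps. Without regions narrower than 100 bp, the median width was 311 bp. The scaffolds with 20 or more regions held 16161 regions with a median gap of 8681 bp. The ratio of observed to random gaps of up to 2000 bp was 1.86. It lay between 1.34 (runs of consecutive names) and 2.30 (a limit of 1000 bp) under 5 alternatives, and stayed past the threshold in each. Every alternative except the runs of consecutive names kept the gaps with a missing number. Those runs were themselves selected by the loss of names, so the alternatives do not test whether voids account for the excess. For gaps of 2000 to 5000 bp the ratio turned from 1.13 over all gaps to 0.921 in runs of consecutive names. For the densest window, the ratio to random placement was 1.24 at 100 kb, 1.32 at 50 kb and 1.14 at 200 kb, with one-sided permutation p-values of up to 0.00995. At 200 kb the densest window held 44 regions, which equalled the highest count among the placements. No paired analysis was possible because the list has no column per library, and for the same reason no replicate could be left out. The settings foreseen for the gut comparison, the shared regions, the genomic distribution, the gene lists, the consensus sites and GC content, and the stricter threshold by score, could not be run on a list without values, genes or sequence. Without read depth, weakly accessible regions cannot be told from strong ones.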

Other observations

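The tests in this part used the region list alone, and those on random removal of names and on the narrow regions were chosen after the result was seen. Runs of consecutive names were added as a setting after the list had been examined, and before their own values were seen. No biological explanation was tested, since the list separates neither gut from whole embryo nor one library from another.

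Short gaps between regions were in excess. Gaps of up to 2000 bp were 1.86 times as frequent as under random placement. Regions whose names are missing from the list would leave voids. In runs of consecutive names, which hold no missing region, the ratio was still 1.34. Numbers were missing more often in sparse stretches, however, so these runs were selected by the same loss. The ratio within them cannot tell whether such voids alone account for the excess. Accessible stretches split into pieces by a region caller would give an excess of the shortest gaps only. The list held no gap shorter than 301 bp, so shorter gaps were not examined. Over all gaps, those of 2000 to 5000 bp were 1.13 times as frequent as under random placement. In runs of consecutive names the ratio was 0.921, which leaves voids and splitting together possible. However, those runs were short, with 17264 gaps in 4164 runs against 26587 gaps on 2049 scaffolds. Each run kept its own summed gap length in the placements, so the lower ratio cannot tell splitting from grouping of regions. The lengths of neighbouring gaps had a Spearman correlation of 0.13 across 24538 pairs (Pearson 0.10). The 1000 shuffles within scaffolds gave 0.04 on average and 0.06 at most. Within runs of consecutive names the Spearman correlation was 0.10 across 13100 pairs (Pearson 0.09), against 0.07 on average and 0.09 at most in shuffles. Short gaps thus lay beside short gaps to a small extent, as stretches that hold several regions would give. Stretches split into several pieces, or voids in sparse stretches, could give the same sign. The correlation therefore cannot tell these explanations apart. Assembly gaps and the position of genes remain open, since no genome of this build was used.

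Numbers were missing from the region names more often in sparse stretches. The mean step between successive numbers was 1.24 times as long in gaps with 1 missing number as in gaps with none (95% scaffold bootstrap interval 1.2005 to 1.2899), which argues against names missing at random with respect to spacing. A loss of more names from sparse scaffolds than from dense ones does not account for it, since the ratio within scaffolds was 1.21 (1.16 to 1.26, 1507 scaffolds). Every one of the 7450 gaps with a missing number was long enough to hold the missing regions at a spacing of at least 301 bp. A candidate explanation is that regions were numbered first and left out later by a criterion that goes with isolation, such as distance from genes or weak signal; the criterion was not tested, and why the numbers are missing is not known.

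Regions narrower than 100 bp lay below a peak of regions of exactly 100 bp, which resembles a minimum length set by a region caller followed by trimming. Trimming at the first base of a scaffold does not account for them, because 0 of the 1298 narrow regions start there. Trimming beside left-out neighbours does not account for the tail either, because 46.3% of the narrow regions (95% scaffold bootstrap interval 43.6 to 49.1%) lie beside no missing number. The share beside one was 53.7% below 100 bp, 59.9% at exactly 100 bp and 50.9% above 100 bp. The difference of 2.78 percentage points between narrow and wider regions (0.10 to 5.40) leaves such trimming open for a small part of them. However, numbers missing between scaffolds were counted too. Narrow regions made up 5.41% of regions farther than 20000 bp from the nearest region, against 3.58% of those within 1000 bp. Numbers were missing more often in sparse stretches, so the difference cannot tell trimming from sparse spacing. An intersection or subtraction of region sets may also have shortened them, which was not tested.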
